A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

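RNA from chemostat cultures of the reference and the null strain was measured on Affymetrix Yeast Genome 2.0 arrays. Per the labels, total RNA was extracted with Qiagen RNeasy kits with DNase treatment on the column, and biotinylated cRNA was made from 5 ug of it. The deposited table holds 1 log2 intensity per probe set and array, as the authors provided it, and the software behind it is not given in the sources used here. The values were tested on the table itself: the lowest value of each array lay between 2.01 and 2.11 and the highest value was 16.

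Of the 10928 probe sets, 166 were controls. A gene symbol was listed for 7244, 1 had several symbols, and 3683 had none listed in the probe table, which dates from 2016. Probe sets were matched to genes of S. cerevisiae by the gene identifier in the probe table, which gave 5498 probe sets and, with the probe set of highest mean kept for each gene, 5449 genes. The array also carries probe sets for another yeast. Probe sets with identifiers of other organisms numbered 1746, lay at the lowest value in 98.5 to 99.7% of cases per array and were not used here. Of the genes tested, 71 were at the lowest value on all 12 arrays.

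The array medians over the tested genes ranged from 10.34 to 10.90, a range of 0.558 log2 units that exceeded the limit of 0.1 set beforehand, so quantile normalization was applied across the 12 arrays. A linear model with 4 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p under 0.05 were called. The 5 contrasts were 20 against 0 min in each strain, the difference between these responses, and the null against the reference strain at each time. Values are log2 differences, with SE from the fit. The fit had 8 residual degrees of freedom with 12 arrays and 4 with 8. The number of arrays limits the precision.

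Of the 35 gene lists written from general knowledge of yeast, 32 had at least 5 measured members and were tested with camera at its preset correlation of 0.01, and again with a correlation estimated from the arrays. The groups, contrasts, threshold, lists and alternatives were chosen before the data were examined. The fit without replicate number 2 in any group, its alternatives, and the chromosome and neighbour analyses were chosen after the data were seen. Of these, only the test of time labels on chromosome I was set before the values of single arrays it uses were seen. No array was moved to another group. Where 1 group lay within 0.25 log2 units of the lowest value of the array, a limit chosen after the data were seen, differences between strains are given as lower bounds of the fold. The limit was applied to the deposited values, and the bound used the normalized value of the gene or, where it lay at the lowest value, the lowest value above it. Chromosome medians used genes with a mean log2 intensity above 6. The neighbour test counted genes within 4 genes of a deleted transporter gene, where STL1, MAL11, MPH2 and MPH3 were counted as deleted from general knowledge of the strain. MPH2 lay at 5.08 to 6.73 on the null arrays, above the lowest value. The source of this signal was not tested, so the deletion of MPH2 is uncertain. The neighbour test was therefore repeated without MPH2 and MPH3. Shares have exact (Clopper-Pearson) intervals, which treat genes as independent and so measure no spread between arrays.

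The pipeline was tested on simulated data with 200 changed genes among 5449. With 12 arrays and the spread of the replicates as labelled, it recovered 9 of 67 genes changed by 1 log2 unit, 30 of 67 changed by 2 and 58 of 66 changed by 4, with 9 false calls. With 8 arrays it recovered 33 of 67, 64 of 67 and 66 of 66, with 5 false calls. The noise was drawn independently for each gene and array, while in the data the replicate 2 arrays lay with the other labelled time. The shares recovered with 12 arrays therefore do not carry over to the fit under the labels, which called no gene over time. The alternatives covered normalization, probe sets, dim genes, the variance model, array weights, a replicate block, thresholds, set tests and the leaving out of replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.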

Results

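Gene expression was measured in 2 strains of the budding yeast Saccharomyces cerevisiae, both of the CEN.PK laboratory background. The null strain carries deletions of the known hexose transporter genes, which encode the membrane proteins that bring glucose into the cell, and the reference strain keeps these genes. Both strains grew in chemostats, continuous cultures held at a fixed growth rate by the feed (dilution rate 0.1 per h), with ethanol as the limiting carbon source. Cells were taken at steady state (0 min) and 20 min after a pulse of glucose. Each strain and time was represented by 3 arrays from replicate cultures, so 12 arrays were compared in 4 groups. The series asks how much of the transcriptional response to glucose needs the sugar to be taken up. After assignment of probe sets to genes, 5449 genes were tested, and the number of arrays limits the precision of every value given here.

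The deleted genes were examined first, since they check the strain labels. Of the 18 hexose transporter genes on the list fixed beforehand, 15 were measured, and HXT6, HXT12 and HXT16 were not analysed here. On all 6 arrays of the null strain, the deposited values of all 15 lay within 0.25 log2 units of the lowest value of the array, with a highest excess of 0.14. Quantile normalization widened the lowest range, and HXT2 reached 2.65 on a null array whose lowest normalized value was 2.06. HXT1, HXT2, HXT3, HXT4, HXT5 and HXT7 lay above that limit on all 6 reference arrays. HXT7 and HXT6 are nearly identical in sequence, so the HXT7 probe set can read both. HXT8, HXT9, HXT11 and HXT14 were above the limit on some reference arrays. For HXT9 this rests on the probe set kept, since another one lay at 2.02 to 2.16 on the 6 reference arrays as deposited. HXT14 was above the limit only on reference 0 min replicate 3, at 3.18 as deposited. HXT10, HXT13, HXT15, HXT17 and GAL2 were near the lowest value on all 12 arrays, and no fold is given for them. With all 12 arrays, limma placed HXT2 lower in the null strain at 0 min by at least 662-fold (adjusted p = 1.44e-05), and the list as a whole was lower at that time by the gene set test camera (adjusted p = 1.81e-08). That call held with a correlation estimated from the arrays (adjusted p = 0.00808 with an estimated correlation).

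The time labels of replicate 2 did not go with those of replicates 1 and 3. HXT1, which encodes a low-affinity glucose transporter induced by glucose, had log2 intensities of 4.76, 13.18 and 5.25 on the reference arrays labelled 0 min, in the order of their replicate numbers. On those labelled 20 min it had 13.20, 4.68 and 13.57. FBP1, the gluconeogenic fructose-1,6-bisphosphatase, had 14.51, 9.33 and 14.66 at 0 min and 9.32, 14.64 and 9.38 at 20 min. In the null strain the repressor gene MIG2 had 3.43, 13.59 and 4.29 at 0 min and 12.84, 3.43 and 12.91 at 20 min. Across genes, which are not independent replicates, the reference array labelled 0 min replicate 2 had a mean correlation of 0.728 with replicates 1 and 3 of its own labelled time and 0.992 with those of the other time. The values for reference 20 min replicate 2 were 0.721 and 0.994. The null arrays had 0.928 and 0.984 for 0 min replicate 2, and 0.942 and 0.992 for 20 min replicate 2.

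**Figure D1:**
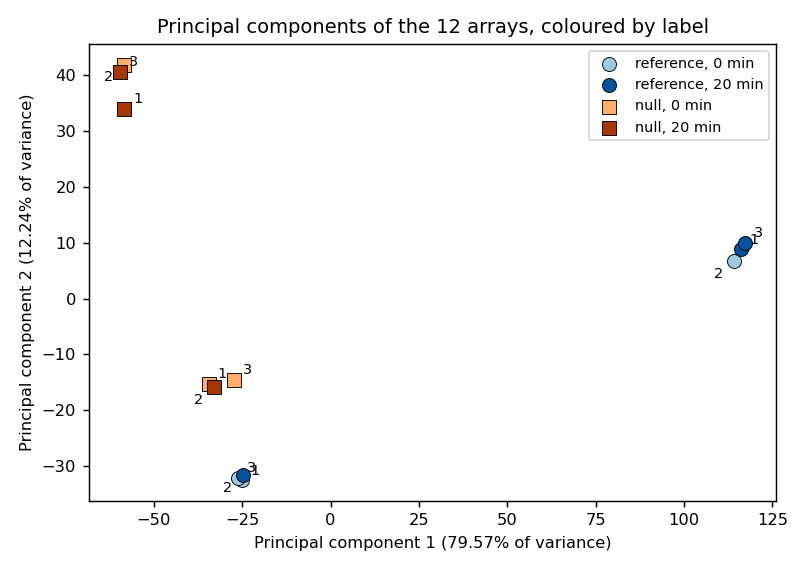
Principal components of the 12 arrays over the 5449 genes, with component 1 (79.57% of the variance) on the horizontal axis and component 2 (12.24%) on the vertical axis, in arbitrary units; circles are reference arrays, squares null arrays, light colours are labelled 0 min, dark colours 20 min, and numbers are replicates. In both strains each replicate 2 array lies beside replicates 1 and 3 of the other labelled time.

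**Figure D2:**
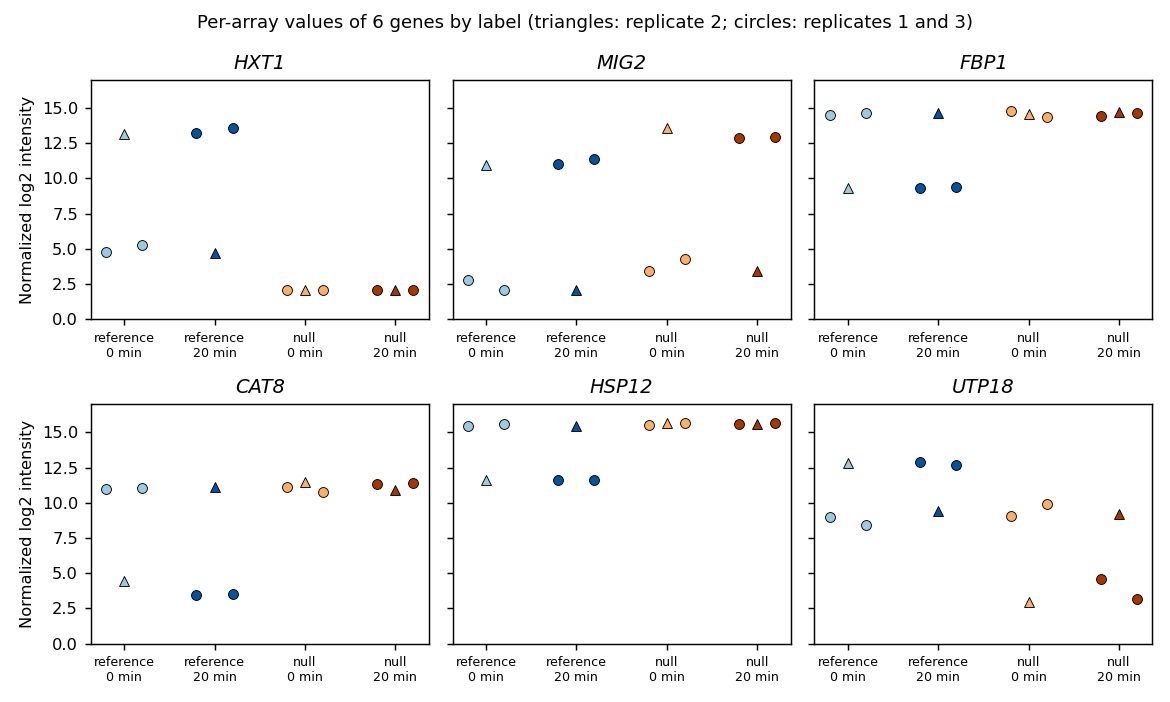
Normalized log2 intensity (vertical axis) of 6 genes on each of the 12 arrays, grouped by labelled strain and time; triangles are replicate 2 and circles are replicates 1 and 3. HXT1 on the reference arrays labelled 0 min lies at 4.76 and 5.25 for replicates 1 and 3 and at 13.18 for replicate 2.

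As a result, the fit of all 12 arrays under the labels as given called no gene in the comparisons over time. By limma, 0 genes changed between 0 and 20 min in the reference strain (16 at an unadjusted p under 0.05), 0 in the null strain (21) and 0 in the difference between their responses (17). Between strains, 25 genes differed at 0 min, 14 higher and 11 lower in the null strain, and 35 differed at 20 min, 20 higher and 15 lower. The balance turned under other settings, with 1 higher and 9 lower at 0 min and 4 and 12 at 20 min as deposited, 3 and 9, and 4 and 12, with arrays centred on their medians, and 2 and 7 at both times with the replicate block. Down-weighting discordant arrays in the same 12-array fit, an alternative chosen before the data were examined, gave the replicate 2 arrays weights of 0.0548 to 0.370 and the other arrays 1.04 to 6.02. It called 4220 genes in the reference strain, 2079 in the null strain and 4045 for the difference. The values given from here on come from the 8 arrays left when replicate number 2 is left out of every group, a choice made after the data were seen. They leave 2 arrays per group and 4 residual degrees of freedom. Of the genes called there, 3891 in the reference strain, 1350 in the null strain and 3565 for the difference were also called with array weights, all with the same sign. The weights leave the weighted fit resting largely on these 8 arrays, so this is no independent evidence. Rose and fell refer below to arrays labelled 20 min against arrays labelled 0 min over replicates 1 and 3, so every direction over time rests on the labels of these arrays. Sizes are uncertain for named genes whose log2 intensity went under 5 in the strain, a limit chosen after the data were seen, since the lowest value was 2.06. Among the changes over time given below, these are BSC1, CAT8, GPH1, HXT1, MIG2, PFK26, PHO84, PXA2 and SOL4 in the reference strain. In the null strain they are ALB1, IPI3, MIG2, PCL1, REX4, SER2, SHQ1 and UTP18.

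In the reference strain, the glucose pulse was followed by a fall of the genes of ethanol-grown, respiring cells. All 10 genes of gluconeogenesis and the glyoxylate cycle fell, with a median log2 change of -4.67. FBP1 fell by 5.24 (SE 0.16), ICL1, the isocitrate lyase of the glyoxylate cycle, by 4.66 (SE 0.16) and PCK1 by 4.22 (SE 0.11), with limma adjusted p of 1.41e-05, 1.60e-05 and 1.14e-05. All 13 genes of ethanol and acetate use fell (median -4.18), among them ADH2, the alcohol dehydrogenase that oxidizes ethanol, by 3.50, and ACS1, an acetyl-CoA synthetase, by 4.82. CAT8, the activator of gluconeogenic genes, fell by 7.48 (SE 0.14, limma adjusted p = 9.57e-06). Of the citric acid cycle genes 18 of 19 fell and 1 did not pass, and CIT1, the mitochondrial citrate synthase, fell by 3.70. Falls were also called for 23 of 26 respiratory chain genes, with 3 not passing, for all 14 genes of the ATP synthase and for 17 of 18 genes of peroxisomes and fatty acid oxidation, with 1 not passing. Among the last, PXA2, a subunit of the peroxisomal fatty acid importer, fell by 8.55 (SE 0.31) to 3.58 and 2.67, close to the lowest value, so the size of its fall is not well determined. Adjusted over the list alone, the counts of these 6 lists were the same, except that 1 respiratory chain gene rose. Camera called all of them lower with its preset correlation (largest adjusted p = 1.73e-06), and none kept its call with an estimated correlation, with adjusted p = 0.107 to 0.212. On the 8 arrays no list passed in any comparison with an estimated correlation, so here and below a lost call does not show that a list was unchanged.

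Reserve carbohydrate and stress genes fell in the same arrays. Of 21 genes of trehalose and glycogen metabolism 19 fell and 2 did not pass, with GPH1, the glycogen phosphorylase, down by 7.53 and TSL1, a subunit of trehalose synthase, by 5.99. All 30 genes of the environmental stress list fell (median -3.86), including HSP12 by 3.92 and the catalase gene CTT1 by 4.75. The proteasome list had 33 of 34 genes down and 1 not passing (median -2.22), led by PRE3 with a fall of 3.83. The autophagy and vacuole list had 14 of 15 down and 1 not passing, with ATG8 down by 4.29. These counts were the same adjusted over the list alone. All 4 lists were lower by camera with the preset correlation, and each call was lost with adjusted p = 0.107 with an estimated correlation. Of the mitochondrial ribosomal protein genes 44 fell, 3 rose and 20 did not pass, and the counts adjusted over the list alone were equal (adjusted p = 0.371 with an estimated correlation).

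Genes of ribosome production rose. All 93 ribosome biogenesis genes were higher at 20 min (median 2.87), among them MAK16, a 60S assembly factor, by 4.33 (SE 0.46), NOP56 by 3.06 (SE 0.36) and NSR1 by 2.53 (SE 0.50), with limma adjusted p of 0.000476, 0.000695 and 0.00577. All 26 genes of RNA polymerases I and III and their factors rose (median 2.42), with RRN7 up by 4.16. Of 127 cytosolic ribosomal protein genes 114 rose and 13 did not pass, with a median of 0.67, and RPL3 at 0.25 did not pass. Translation factors had 30 up, 1 down and 3 not past the threshold, and tRNA synthetases 18, 1 and 1, with WRS1 up by 2.40. Purine and one-carbon genes had 15 up, 1 down and 5 not past it, with IMD4, an IMP dehydrogenase, up by 5.33. Adjusted over the list alone, 115 cytosolic ribosomal protein genes and 16 purine genes rose, and the other counts stayed equal. All 6 lists were called higher by camera with the preset correlation and none with an estimated one. The adjusted p = 0.292 with an estimated correlation for ribosome biogenesis, 0.241 for the polymerases, 0.421 for ribosomal proteins, 0.156 for purines and 0.107 for the remaining lists.

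Glucose transport and sensing genes moved both ways in the reference strain. HXT1 rose by 8.38 (SE 0.20), HXT3 by 5.38 (SE 0.11) and HXT4 by 4.04 (SE 0.16), while HXT5 fell by 4.39 (SE 0.13), HXT7 by 3.52 (SE 0.19) and HXT2 by 0.98 (SE 0.26). Of the 15 measured transporters 3 rose, 6 fell and 6 did not pass, also when adjusted over the list alone. The glucose sensor genes went apart, with SNF3, the high-affinity sensor, down by 4.16 and RGT2, the low-affinity sensor, up by 1.52. MIG2 rose by 8.76 (SE 0.36) and MIG3 by 4.85 (SE 0.20); both encode repressors of glucose-repressed genes. STD1 rose by 4.37 and its paralog MTH1 fell by 3.33, both encoding corepressor proteins of the sensor pathway. Over the whole list of sensors and signalling genes, 11 rose, 19 fell and 12 did not pass, unchanged when adjusted over the list alone (camera adjusted p = 0.244, and adjusted p = 0.646 with an estimated correlation). In glycolysis 3 genes rose, 10 fell and 5 did not pass, equal when adjusted over the list alone, and the median of -0.49 turned to 0.22 with arrays centred on their medians. PFK27, which makes the glycolytic activator fructose 2,6-bisphosphate, rose by 5.73, and PFK26, which does the same, fell by 6.86. Camera called this list lower (adjusted p = 0.00895), a call lost with adjusted p = 0.345 with an estimated correlation.

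Over all genes, 3940 of 5449 (72.3%) changed in the reference strain by limma, 2140 up and 1800 down, and 2864 of these by at least 1 log2 unit, 1505 up and 1359 down. BSC1 rose by 9.22 (SE 0.09) from 2.58 and 2.73, close to the lowest value, so the size of its rise is not well determined. The quantile normalization left a median change over all genes of 0.13, against -0.38 for the values as deposited, which gave 1419 genes up and 2491 down. Small changes therefore depended on the scaling for their sign, while the ribosome biogenesis list had all 93 members up under both.

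In the null strain the pulse was followed by changes in fewer genes, and the genes of ethanol growth did not show the fall seen in the reference strain. Of the 10 gluconeogenic genes 0 passed the limma threshold, where 1501 of all 5449 genes did (2244 at an unadjusted p under 0.05). Their median of -0.06 turned to 0.24 with arrays centred on their medians. FBP1 was at -0.05 (SE 0.16), ICL1 at -0.06 (SE 0.16) and PCK1 at 0.00 (SE 0.11). Among ethanol and acetate genes 1 rose and 1 fell of 13, and CAT8 at 0.44 and HSP12 at 0.05 did not pass. HSP12 started at 15.52 and 15.64, close to the highest value of 15.84, so a fall could have been seen but a large rise could not. MIG2, however, rose by 9.02 (SE 0.36, limma adjusted p = 0.000704) and MIG3 by 4.71 (SE 0.20, adjusted p = 0.000819), and MIG1, which encodes the main glucose repressor, rose 2.64-fold (adjusted p = 0.00244). STD1 rose by 2.17 and MTH1 by 2.30. The bZIP factor gene CIN5 rose by 5.92 (SE 0.39) and ALD3, a stress-induced aldehyde dehydrogenase, by 3.61 (SE 0.34). PCL1, a G1 cyclin of the Pho85 kinase, fell by 7.43 (SE 0.09, limma adjusted p = 7.71e-06) to 2.71 and 2.69, close to the lowest value, so the size of its fall is not well determined.

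Part of the ribosome production genes were called lower in the null strain. Of the 93 ribosome biogenesis genes 59 fell, none rose and 34 did not pass, with a median of -1.24, and 64 fell adjusted over the list alone. UTP18, a factor of the small-subunit processome, fell by 5.58 (SE 0.54), ALB1, a 60S assembly factor, by 4.81 (SE 1.04) and NSR1 by 2.43 (SE 0.50). Of the 26 polymerase I and III genes 14 fell, 2 rose and 10 did not pass, with 16 falling and 2 rising adjusted over the list alone, and RPA12, a polymerase I subunit, fell by 4.35. Of the Gcn4-regulated amino acid synthesis genes 22 of 42 fell and none rose (23 adjusted over the list alone), with HOM3, the aspartate kinase, down by 2.78. Sulfur and methionine genes had 13 of 22 down and none up (14 adjusted over the list alone), with SUL2, a sulfate permease, down by 3.86 and MET16 by 3.60. The tRNA synthetases had 8 of 20 down and none up (9 adjusted over the list alone). Camera with the preset correlation called these 5 lists lower (largest adjusted p = 0.00362). None was called with an estimated correlation, at adjusted p = 0.434 with an estimated correlation for ribosome biogenesis, the polymerases and sulfur genes and 0.369 for the remaining 2.

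In other lists a minority of members passed as higher in the null strain, where 702 of all 5449 genes did. Of 67 mitochondrial ribosomal protein genes 19 rose, 48 did not pass and none fell, and 21 rose adjusted over the list alone, while with values as deposited 7 rose and 1 fell. Peroxisome and fatty acid oxidation genes had 7 of 18 up and none down (9 adjusted over the list alone), with PXA2 up by 1.45. The trehalose and glycogen list had 4 of 21 up, 2 adjusted over the list alone, and the respiratory chain 5 of 26, 4 adjusted over the list alone and 2 with values as deposited, with COX5B up by 2.06. Of 8 sucrose and maltose genes 3 rose, with equal counts adjusted over the list alone, among them IMA1, an isomaltase, by 2.83 and the maltose permease gene MAL31 by 2.18. All 5 lists were called higher by camera with the preset correlation (largest adjusted p = 0.0131), and each had an adjusted p = 0.434 with an estimated correlation. Of the 30 stress genes 5 rose, 2 fell and 23 did not pass, equal when adjusted over the list alone, with CTT1 up by 1.23 and SSA4, a heat-induced Hsp70, down by 1.22. Where 799 of all 5449 genes fell, 18 of 127 cytosolic ribosomal protein genes did, a similar share, and none rose (14 fell adjusted over the list alone). Their median of -0.16 turned to 0.11 with arrays centred on their medians, and the camera call was lost at adjusted p = 0.690 with an estimated correlation.

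Over all genes, limma called 1501 in the null strain (27.5%), 702 up and 799 down, of which 798 changed by at least 1 log2 unit. The balance depended on the scaling, with 250 up and 1183 down in the values as deposited, where the median change over all genes was -0.13. Leaving out each of the 4 null arrays in turn gave 1049 genes without 0 min replicate 1, 873 without 0 min replicate 3, 960 without 20 min replicate 1 and 750 without 20 min replicate 3. A fit of these 4 arrays alone called 564, 293 up and 271 down. With the replicate block on the 8 arrays 796 were called, 352 up and 444 down.

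The difference between the responses was tested directly. Limma called 3611 genes, 1765 with the response of the null strain above that of the reference strain and 1846 with it below. This balance turned with values as deposited, with 2130 above and 1596 below, and with centred arrays, with 1940 and 1867. All 10 gluconeogenic genes differed upwards (median difference 4.54), as did all 13 ethanol and acetate genes (median 3.99) and 29 of 30 stress genes (median 3.90). All 93 ribosome biogenesis genes differed downwards (median -3.89), with UTP18 at -9.65 (SE 0.77, limma adjusted p = 0.000238), as did 24 of 26 polymerase I and III genes (median -3.37). These 5 counts were equal adjusted over the list alone. For MIG2 the difference was 0.26 (SE 0.51, limma adjusted p = 0.684) and for MIG3 -0.14 (SE 0.29, adjusted p = 0.699), so no difference was called for either. MIG2 lay close to the lowest value on the reference arrays labelled 0 min, at 2.82 and 2.10, so the size of its rise there, and with it this difference, is not well determined. Camera called 23 of 32 lists with the preset correlation and 0 with an estimated correlation, where the smallest value was adjusted p = 0.108 with an estimated correlation, shared by 8 of the lists among them ethanol use and stress.

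The genes called in each strain overlapped mostly in opposite directions. Of the 2140 genes up in the reference strain, 555 were down in the null strain where independent lists would share 314, and 273 were up where 276 would be shared. Of the 1800 genes down in the reference strain, 274 were up in the null strain where 232 would be shared, and 104 were down where 264 would be. Altogether 829 genes changed in opposite directions with a called difference, and 377 changed in the same direction. Across genes, which are not independent replicates, the changes of the 2 strains had a Pearson r of -0.232 and a Spearman rho of -0.237, with a slope of -0.10. Without any use of time labels, the median range of a gene over the 6 arrays of a strain was 1.43 log2 units in the reference strain and 0.81 in the null strain. The range exceeded 2 for 1859 genes in the reference strain and 604 in the null strain.

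**Figure D3:**
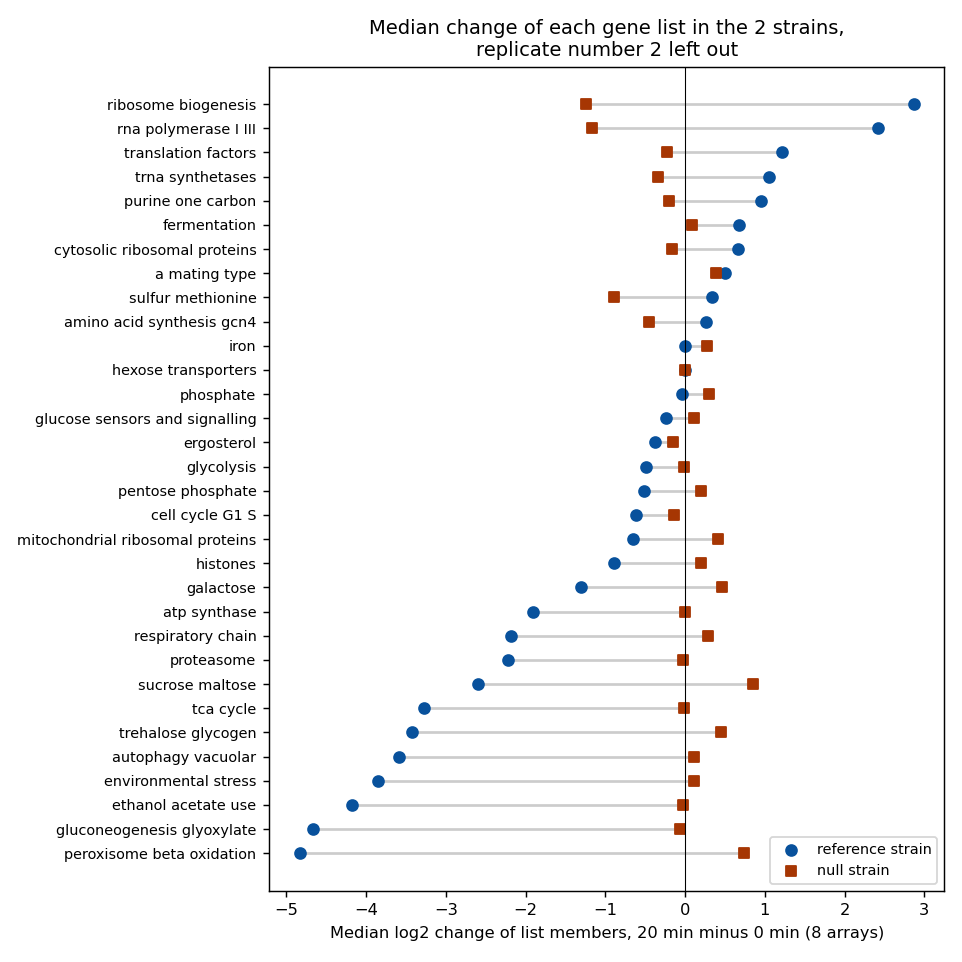
Median log2 change of the members of each tested gene list, 20 min minus 0 min by label over the 8 arrays without replicate number 2 (horizontal axis), for the reference strain (circles) and the null strain (squares); lines join the 2 strains. Ribosome biogenesis lies at 2.87 in the reference strain and -1.24 in the null strain, and gluconeogenesis at -4.67 and -0.06, the last of which turned to 0.24 with arrays centred on their medians.

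Before the pulse few genes passed the threshold between the strains, and with 2 arrays per group a gene not called may still differ. At 0 min limma called 70 genes on the 8 arrays, 48 higher and 22 lower in the null strain (859 at an unadjusted p under 0.05). The balance of directions reversed with values as deposited, with 13 higher and 28 lower, and was 60 and 2 without the dimmest 25% of genes. The lower genes were led by transporters, with HXT5 at least 6833-fold, HXT7 at least 3499-fold and HXT2 at least 928-fold lower. These folds were measured against the value of the gene itself near the lowest value, or the lowest value above it where the gene lay at it. STL1, a glycerol transporter, was at least 3151-fold lower and MAL11, a maltose and trehalose transporter, at least 780-fold. Genes that encode no transporter were also near the lowest value in the null strain, with REE1, linked to galactose metabolism, at least 2448-fold and DLD3, a lactate dehydrogenase, at least 2050-fold lower. URA3, of uracil synthesis and a common selection marker, was lower by a log2 value of -5.77 (SE 0.22, limma adjusted p = 0.000311). Within the hexose transporter list 7 of 15 were lower and none higher, 9 adjusted over the list alone (camera adjusted p = 2.23e-12, and adjusted p = 0.0884 with an estimated correlation). No gene of the gluconeogenic, ethanol use, stress, ribosome biogenesis or polymerase lists passed by limma at this time, and FBP1 differed by 0.01 (SE 0.16). The count rested on single arrays, with 17 genes without reference 0 min replicate 1, 21 without reference replicate 3, 68 without null replicate 1 and 13 without null replicate 3, and with 10 genes in a fit of these 4 arrays alone.

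Genes of chromosome I were higher in the null strain as a group. Of the 48 genes called higher at 0 min, 30 lay on chromosome I and 5 in the left end of chromosome XIV, and 13 on neither. The 76 chromosome I genes with a mean log2 intensity above 6 had a median difference of 0.98 at 0 min and 0.72 at 20 min. Of these, 62 (81.6%, exact 95% interval 71.0 to 89.5%) were higher by over 0.5 at 0 min. The interval treats genes measured on the same arrays as independent. The other 15 chromosomes had medians from -0.04 to 0.03, but a part of chromosome XIV was also higher. Its 9 genes from the left end to VNX1 had medians of 0.99 at 0 min and 1.17 at 20 min. The next 9 genes inwards had 0.13 and 0.05. This part was chosen after the data were seen. Among the called genes were SYN8, a syntaxin-related protein, at 1.87 (SE 0.14), SEN34, a subunit of the tRNA splicing endonuclease, at 1.72 (SE 0.14) and SPO7 at 1.66 (SE 0.10). Relative to the other chromosomes, the chromosome I median of each array was between 0.242 and 0.675 on the 6 null arrays and between -0.453 and -0.334 on the 6 reference arrays (exact permutation test of 6 against 6, two-sided p = 0.00216, the smallest 12 independent arrays allow). The chromosome was chosen for its pattern, and the 2 times of a replicate number may share a culture. With the 2 arrays of each strain and number averaged, the exact permutation p was 0.1, the smallest that 3 against 3 allow. Neither comparison uses a time label.

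**Figure D4:**
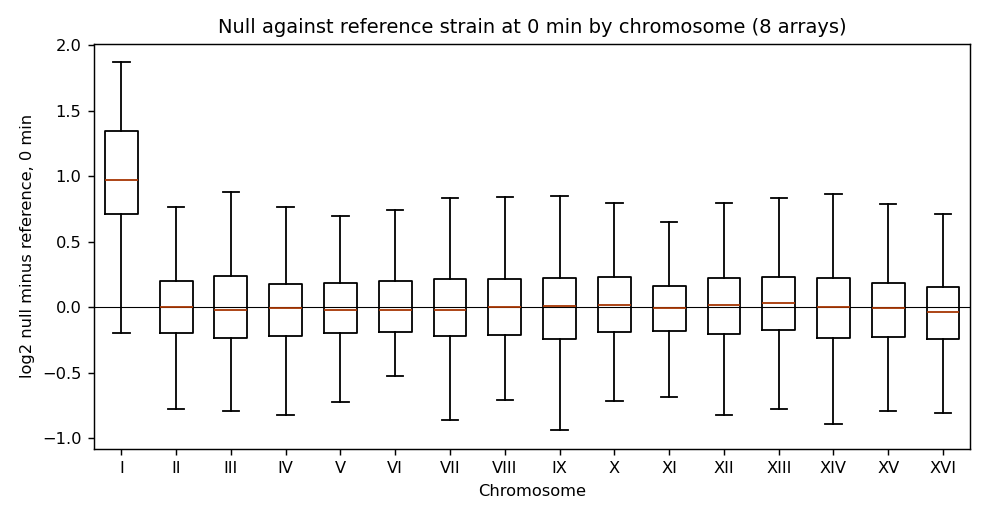
Log2 difference between the null and reference strains at 0 min (vertical axis) for genes of each chromosome (horizontal axis) with a mean log2 intensity above 6, over the 4 arrays labelled 0 min without replicate number 2; lines are medians, boxes run from the lower to the upper quartile and whiskers reach up to 1.5 box lengths, with genes beyond them not drawn. Chromosome I has a median of 0.98, and the other chromosomes lie between -0.04 and 0.03.

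At 20 min the strains stood far apart. Limma called 4106 genes on the 8 arrays, 1991 higher and 2115 lower in the null strain. This balance turned with values as deposited, with 2220 higher and 1915 lower, and with centred arrays, with 2129 and 2104. HXT3 was at least 3376-fold, HXT1 at least 2568-fold and HXT4 at least 2228-fold lower in the null strain. Genes of respiration and fatty acid oxidation were higher there, with all 26 respiratory chain genes (median 2.30) and all 18 peroxisomal genes (median 5.45) passing, and PXA2 was higher by 10.07 (SE 0.31, limma adjusted p = 8.25e-06), a size that rests on reference arrays close to the lowest value. All 10 gluconeogenic genes (median 4.46) and all 30 stress genes (median 3.96) were higher as well, with FBP1 at 5.19. All 93 ribosome biogenesis genes were lower (median -3.89), with UTP18 at -8.89, as were all 26 polymerase I and III genes (median -3.26) and 110 of 127 cytosolic ribosomal protein genes (median -0.76). Adjusted over the list alone, 112 of the ribosomal protein genes were lower and the other counts were equal. Camera called 23 of 32 lists with the preset correlation and none with an estimated one, where the smallest was adjusted p = 0.114 with an estimated correlation. With all 12 arrays and the labels as given, 35 genes passed, and 3046 passed when reference 20 min replicate 2 alone was left out.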

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

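All tests in this part were chosen after the results were seen, except the test of the normalization, the test of time labels against the chromosome I values and the counts of splits between the strains.

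The difference between the responses of the 2 strains was singled out because its own test in limma, on the 8 arrays without replicate number 2, called 1765 genes with the null response above that of the reference strain and 1846 below. The values as deposited turned the balance, with 2130 above and 1596 below. Of the tested lists, 23 were called by camera with the preset correlation, and 0 with an estimated correlation. The median difference, null minus reference, was 4.54 for gluconeogenesis, 3.99 for ethanol and acetate use, 3.15 for the citric acid cycle, 2.36 for the respiratory chain, 1.84 for the ATP synthase and 5.49 for peroxisomes. It was 0.44 for glycolysis, which was 0.27 as deposited and 0.01 with arrays centred on their medians. It was 4.13 for trehalose and glycogen, 3.90 for stress genes, 2.37 for galactose, 3.11 for sucrose and maltose, 2.22 for the proteasome, 3.69 for autophagy, 1.22 for histones and 1.12 for mitochondrial ribosomal proteins. Among the called lists, those with a negative median were ribosome biogenesis at -3.89, RNA polymerases I and III at -3.37, sulfur and methionine at -1.67, translation factors at -1.54, purines at -1.24, tRNA synthetases at -1.19, cytosolic ribosomal proteins at -0.83 and amino acid synthesis at -0.58.

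Among named genes called in opposite directions in the 2 strains, the difference was 5.97 for CTT1, 5.63 for MTH1, 5.13 for FMP48 and 4.61 for ALD3. The factors of ribosome assembly and the nucleolus had -9.65 for UTP18, -9.61 for REX4, -8.40 for IPI3, -8.17 for ALB1, -8.13 for SHQ1, -7.79 for RPA12 and -4.96 for NSR1. The sizes for UTP18, REX4, IPI3, ALB1 and SHQ1 are uncertain, as is that for SER2, since these genes went under a log2 intensity of 5 in the null strain. SER2, of serine synthesis, had -8.25, the mitochondrial carrier OAC1 had -6.19 and the sensor RGT2 had -2.11.

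The arrays of replicate number 2 lay with the other labelled time in both strains. Each of these 4 arrays correlated more with replicates 1 and 3 of the other time than of its own, by at least 0.0503, which restates the pattern and so decides nothing about exchanged time labels. A batch that moved both replicate 2 arrays of a strain the same way would make their deviations from their groups correlate positively. The higher of the 2 correlations across genes was -0.885. Such a batch alone would not place the arrays this way, but the correlation follows from that place and is no separate test. A replicate culture that behaved differently could lie outside the arrays of the other time, and the highest ratio of distances was 1.06. This ratio restates that the arrays lay with the other time, so it cannot exclude such a culture. Exchanged labels stay open as a hypothesis that may explain the pattern, and the values here hold no test of it.

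All 93 ribosome biogenesis genes rose in the reference strain, and 59 of them fell in the null strain. The normalization does not account for it, since without it the list fell by 1.43 in the null strain relative to all genes. A weaker copy of the reference response would give a positive correlation across genes, but r was -0.232. A general stress response of the null strain would raise most stress genes, and 16.7% of that list rose. The 15 brighter members, however, started at 14.06 or above with 15.84 as the highest value. Of the 15 dimmer ones 5 rose (33.3%, exact 95% interval 11.8 to 61.6%). That interval treats genes as independent, and a general stress response stays open. A response of the null strain to extracellular glucose without uptake may underlie the opposite movement, as a hypothesis that these tests leave open, and it also rests on the time labels of replicates 1 and 3.

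Chromosome I genes were higher in the null strain. Exchanged time labels cannot produce this, because all 6 null arrays lay above all 6 reference arrays. A few strongly changed genes were also argued against, as 81.6% of the genes were higher by over 0.5. An extra copy of chromosome I predicts a shift of about 1 along the whole chromosome, and the median was 0.98 at 0 min, with 0.95 in the left part and 1.08 in the right part. At 20 min it was 0.72, with 0.52 in the left part, under the predicted range, and 0.80 in the right part, so an extra copy stays open as a hypothesis that may explain the pattern.

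Other splits of the arrays were counted for each comparison. In the reference strain all 10 splits of the 6 arrays gave at least the labelled count of 0 genes by limma (16 at an unadjusted p under 0.05), and the highest other split gave 4387. That split put 0 min replicates 1 and 3 with 20 min replicate 2, which points to a structure of the arrays. In the null strain all 10 splits gave at least the labelled 0 (21 unadjusted), and the highest other gave 2159, with the same replicates together. For the difference, all 100 drawn splits gave at least the labelled 0 (17 unadjusted), with 4068 as the highest other. Any split reaches a count of 0, so these 3 tests say nothing about chance. Between the strains 1 of 10 splits, the labelled one, gave as many genes, with 6 at 0 min and 5 at 20 min on the arrays compared and 0 as the highest other at both times. With 10 splits the share is never small enough to decide.

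Outside the tested genes, 221 of 3517 probe sets with no gene name listed, controls excluded, lay above the lowest value on all 12 arrays. Any excess over the lowest value was counted here, without the limit of 0.25 log2 units used for the transporters. The count can therefore include background. These probe sets were singled out as data the comparisons did not use.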

How the results depend on the processing

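The fits without number 1, 2 or 3 and all alternatives on 8 arrays were chosen after the data were seen, and the other alternatives before. The planned floors on low values were not run, because the table is on the log2 scale.

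With all 12 arrays, 25 genes differed between the strains at 0 min and 35 at 20 min by limma. Values as deposited gave 10 and 16, and arrays centred on their medians gave 12 and 16. Leaving out the dimmest 25% of genes gave 3 and 0 (178 and 1688 at an unadjusted p under 0.05), and every probe set gave 21 at 20 min. A fit of only the arrays compared gave 6 and 5, the replicate block gave 9 and 9, and an adjusted p under 0.01 gave 14 and 15. The causes were not tested, beyond the fewer arrays of the fits that leave arrays out. Deviations of arrays with the same number correlated from -0.984 to -0.590 across genes within a strain and from -0.255 to -0.0310 between strains. The place of the number 2 arrays forces the values within a strain below 0, so they do not show whether the numbers pair cultures.

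Settings that discount replicate number 2 changed the counts over time. Array weights gave 4220 genes in the reference strain, 2079 in the null strain, 4045 for the difference, 138 at 0 min and 4541 at 20 min. Number 2 left out of every group gave 3940, 1501, 3611, 70 and 4106. Number 1 left out gave 0 genes in the reference strain, the null strain and the difference by limma (1, 3 and 1 at an unadjusted p under 0.05), and 1 gene at 0 min and 1 at 20 min. Number 3 left out gave 0 in the reference strain, the null strain and the difference (0, 17 and 5 unadjusted), and 0 at 0 min and 0 at 20 min (124 and 149 unadjusted). Leaving out single arrays gave 0 to 1 genes in the reference strain, 0 in the null strain and for the difference, 13 to 20 at 0 min and 12 to 3046 at 20 min, the highest without reference 20 min replicate 2. A lone array left in a group was assumed to vary like the other groups.

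The correlation of the responses across genes, -0.230 with 12 arrays, was -0.314 as deposited and -0.314 with centred arrays, -0.344 without the dimmest 25% and -0.0232 with number 3 left out. It reversed to 0.0537 with number 1 left out, and the cause was not tested. Leaving out single arrays gave -0.253 to -0.0708. With 8 arrays it was -0.232, and -0.354 as deposited, -0.354 centred, -0.356 without the dimmest 25% and -0.274 to -0.173 with single arrays left out.

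With 8 arrays, 70 genes differed at 0 min and 1501 changed in the null strain. At 0 min the count was 41 as deposited, 18 with every probe set, 10 with only the arrays compared, 44 with the replicate block, 111 with trend and robust moderation and 22 at an adjusted p under 0.01. In the null strain it was 687 with every probe set, 564 with only the arrays compared, 796 with the replicate block, 500 at an adjusted p under 0.01 and 798 with a log2 change of at least 1. Leaving out single arrays gave 3419 to 3622 genes in the reference strain, 750 to 1049 in the null strain, 3175 to 3474 for the difference, 13 to 68 at 0 min and 3693 to 3783 at 20 min. The counts of the reference strain, the difference and 20 min stayed within 1.5 times under every alternative run on 8 arrays. Direction was checked for the most changed genes, the single genes fixed beforehand and the transporters, and not for genes named only as list members. No checked gene that was called on the 8 arrays reversed its direction under these alternatives. Changes of sign in genes not called were not counted. Over the checked genes and alternatives, calls were lost 93 times at 0 min, 43 in the null strain, 30 in the reference strain, 10 for the difference and 2 at 20 min.

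The lists called by camera with 12 arrays numbered 20 in the reference strain, 12 in the null strain, 22 for the difference, 20 at 0 min and 22 at 20 min. With an estimated correlation they numbered 0, 0, 0, 1 and 0, and fry gave 0, 0, 0, 2 and 2. Number 1 left out gave 2, 4 and 3 for the first 3 comparisons, number 3 left out gave 0, 4 and 3, and number 2 left out gave 7 at 0 min. Leaving out single arrays gave 17 to 21, 4 to 12, 17 to 22, 5 to 22 and 22 to 23, with 5 at 0 min without reference 0 min replicate 2. With 8 arrays 21, 13, 23, 7 and 23 lists were called, and 0 in all 5 comparisons with an estimated correlation. At 0 min fry called 3 and the values as deposited 11, and single arrays left out gave 8 to 15 in the null strain.

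Signal over background limited the transporters: 15 were near the lowest value on the null arrays. Differences are lower bounds where a gene lay above it on the reference arrays, and no fold is given for the 5 near it on all 12 arrays.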

Other observations

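The tests in this part were chosen after the result was seen.

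Other gene lists fixed beforehand gave these values on the 8 arrays without replicate number 2. In the reference strain, sucrose and maltose genes had 0 up, 6 down and 2 not past the threshold (adjusted p = 0.292 with an estimated correlation), and histones had 0, 6 and 3 (adjusted p = 0.310 with an estimated correlation). Ergosterol genes had 3 up, 14 down and 7 not past it in the reference strain (adjusted p = 0.434 with an estimated correlation), with a median of -0.38 that turned to 0.09 with centred arrays. In the null strain they had 0, 3 and 21 (adjusted p = 0.630 with an estimated correlation), with a median of -0.15 that turned to 0.05. UPC2, a regulator of sterol genes, rose by 2.49 in the reference strain and fell by 2.13 in the null strain. Translation factors in the null strain had 0 up, 8 down and 26 not past it (adjusted p = 0.434 with an estimated correlation), with 0 up and 2 down adjusted over the list alone. Adjusted over the list alone, the sucrose, histone and reference ergosterol counts were equal, and 2 ergosterol genes fell in the null strain.

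Lists not called by camera in the reference strain gave directions that depended on the scaling in part. Phosphate genes had 4 up and 5 down of 15, with 2 up and 5 down adjusted over the list alone and 1 up and 10 down with values as deposited, and the phosphate transporter PHO84 rose by 5.77 from 2.81 and 2.56, close to the lowest value, so the size is not well determined. Iron genes had 4 up and 4 down of 21, with 3 up and 4 down adjusted over the list alone and 1 up and 13 down as deposited. Galactose genes had 1 up and 4 down of 7, and G1/S genes 3 up and 10 down of 21, both equal adjusted over the list alone, while as deposited they had 0 up and 6 down, and 2 up and 15 down. Fermentation genes had 8 up and 5 down of 13 and pentose phosphate genes 4 up and 6 down of 11, also equal adjusted over the list alone, with the decarboxylase PDC5 up by 3.79 and SOL4 at -7.18, of uncertain size because it ended at 6.17 and 3.74. The a mating type list had 2 up and 1 down of 7, with 1 up and 1 down adjusted over the list alone, and of the 4 alpha mating type genes 2 rose, 1 adjusted over the list alone, with a median of 0.43 that turned to -0.05 with centred arrays, and 2 fell with values as deposited.

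In the null strain iron genes had 5 up and 1 down of 21, G1/S genes 2 up and 7 down of 21, and galactose genes 2 up and 0 down of 7. Adjusted over the list alone, the G1/S counts were 2 up and 8 down and the iron and galactose counts were equal. With values as deposited the galactose calls turned to 0 up and 1 down, the G1/S calls to 0 up and 9 down and the iron calls to 3 up and 2 down. FIT1, a cell wall mannoprotein of iron uptake, rose by 2.49, GAL1 by 2.00 and the ribonucleotide reductase gene RNR1 fell by 2.52.

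Genes that encode no transporter were also lower in the null strain at 0 min, and 7 of these 13 lay within 4 genes of a deleted transporter gene (odds ratio 74.4, Fisher's exact test, two-sided p = 4.29e-10). With MPH2 and MPH3 not counted as deleted the counts were equal (odds ratio 73.6, Fisher's exact test, two-sided p = 4.64e-10). Both tests treat genes as independent, but DLD3, RMD6 and DSF1 share the HXT13 locus. REE1, YJL218W and IMA5 likewise lie together on chromosome X. Genes of a shared region were thus counted separately, so these p-values overstate the evidence. DLD3, at least 2050-fold lower, RMD6, at least 67.5-fold, and DSF1, at least 15.5-fold, lay beside HXT13. REE1, at least 2448-fold lower, and YJL218W, at least 14.6-fold, lay beside HXT9, IMA5, at least 23.3-fold lower, beside HXT8, and VTH1, with a log2 difference of -2.40, beside HXT12. Loss of chromosome regions around the deleted genes may explain their low values, as a hypothesis. The 6 genes not near one were FMT1, MST27, RPR2, SNU56, URA3 and YBL100W-A.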
